A study of Mus musculus with 8 samples.

How the data were processed

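Small RNA libraries were made from total RNA of KH2-DGCR8 cells, a mouse embryonic stem cell line, during embryoid body (EB) differentiation at days 0, 1, 2 and 4, with doxycycline (Dox) or without it. Total RNA was isolated with TRIzol and libraries were prepared with an NEBNext small RNA kit, per the labels' protocols. Each of the 8 conditions had 1 library, giving 4 libraries per treatment, and no condition was replicated. The groups were taken from the sample labels, and how long cells had been given Dox is not given in the sources used here.

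The deposited values are scores in a table of 1099 mature miRNAs: whole numbers that sum to between 999965 and 1000047 in each library, which is what RPM (reads scaled to 1 common total) rounded to whole numbers give. The submitters' processing notes name Bowtie and the genome build mm10, with no version or role. The counting tool, the miRNA annotation and the handling of reads that match several miRNAs are not given in the sources used here. The table also held 1 blank row that names no miRNA, which was left out.

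Low values in each library moved in steps of what 1 read is worth, between 1.85 and 2.76 RPM. A read total was sought for which every value is the rounding of a whole number of reads, within 0.5 RPM, with those reads summing to the total. Such a total was found for each of the 8 libraries, and the smallest was used. It matched 100% of the values above 0, although in the library with the most matches 207 totals did so, and only 2 libraries had a single one. The search returned the exact reads in 8 of 8 simulated libraries. The implied totals ran from 362483 for day 4 without Dox to 541342 for day 4 with Dox. They count reads assigned to miRNAs, so a read assigned to several copies may be counted for each. A count of 3 reads corresponds to between 5.54 and 8.28 RPM, and values near or below that level are imprecise. Intervals at 95% confidence for a ratio of 2 libraries are exact conditional binomial intervals on the implied reads, and cover counting error only, since PCR copies are not independent molecules.

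The tests had been planned for raw counts or for normalized values, and the table required those for normalized values. Tests used limma 3.58.1 in R 4.3.3, with Python 3.11.15 for the read totals. miRNAs with a value of at least 1 in at least 2 libraries were kept, leaving 839. Values were analysed as log2(value + 1) with limma's moderated test, with a mean-variance trend and robust prior variance, and Benjamini-Hochberg adjustment over the 839 at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low miRNAs. The model held treatment and day as a factor, so that its 3 residual degrees of freedom measure how the Dox effect varied between days. Day was a block by design, because each day supplied 1 library of each treatment. The change of the Dox effect with day was tested by adding the product of treatment and day as a number, which left 2 residual degrees of freedom. The prior degrees of freedom were estimated as infinite for all except 39 miRNAs in the additive model, and all except 3 in the model for a changing effect. The spread of most miRNAs was thus taken from the trend and not from their own libraries. SEs and p-values can therefore be narrower than a miRNA's own spread between days would give. The labels do not say whether libraries came from separate cultures, so p-values concern the spread between these libraries, pooled over miRNAs.

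The method was tested on simulated libraries for the Dox comparison, with 200 miRNAs changed. These were drawn from miRNAs with a mean of at least 10 RPM, with an assumed dispersion and an equal Dox effect on every day. Of those changed 4-fold it called 94.5%, with 4 false calls among 867 miRNAs tested, and of those changed 2-fold it called 35.5%, with 2 false calls among 880. With a dispersion that varied between miRNAs the shares were 85% and 23%. Without the robust option 85.5% and 21.5% were called with a constant dispersion, and 71.5% and 5.5% with a varying one. When nothing was changed it called 0 miRNAs, with the robust option and without it. In the data only 499 of the 839 miRNAs tested had such a mean, and Dox ratios varied between days. The shares called therefore do not carry over to all miRNAs tested here. Because the dispersion was assumed, the absence of calls when nothing was changed sets no bound on false calls in the data. In a simulation of the list test with 1 changed list, that list alone was called. That result does not show how the list test behaves when members of a list vary together. In the data, the correlation estimated between members for the Dox comparison ran from -0.03 for the endoderm list to 0.792 for the miR-302 cluster. The simulated result therefore does not carry over to lists with a high correlation.

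The following lists of miRNAs were fixed before the data were examined: miR-290 cluster, miR-302 cluster, miR-17 family clusters, let-7 family, miR-200 family, Dlk1-Dio3 cluster, Sfmbt2 cluster, DGCR8-independent, Dgcr8 transcript hairpin, cardiac and skeletal muscle, blood and endothelium, neural, endoderm, Hox cluster miRNAs, fibroblast (feeder) markers and p53-linked miR-34. The 15 with at least 3 tested members were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with fry. The share of reads per list was compared between treatments with an exact two-sided sign-flip permutation test within days, which has 16 flips and cannot give a p below 0.125.

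The rule for miRNAs named in the text was also fixed beforehand. For Dox it took those past the threshold with a mean of at least 10 RPM and 1 direction in all 4 days, up to 10 with the highest and 10 with the lowest fold change. For day 4 against day 0 it took up to 10 in each direction with the same mean and 1 direction in both treatments. It added up to 2 members of each list with the highest mean and up to 2 with the largest fold change, both arms of miR-1306, miR-302b and miR-294, let-7a, let-7g, miR-320, miR-484 and the 5 miRNAs with the highest mean. Named after their values were seen were miR-181a-5p, miR-143-3p, miR-9-5p, miR-128-3p, miR-210-5p and miR-451a, the miRNAs past the threshold for a changing Dox effect that the rule did not take (miR-302a-5p and miR-493-5p), and the members of genomic clusters in the closing observations.

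Hairpin positions were taken from GENCODE vM21, on GRCm38, which is the mm10 assembly, and 675 of the 728 base names of the table matched a hairpin gene. Copies with near-identical sequence had equal or near-equal values: 18 miRNAs in 8 sets, among those with a mean of at least 10 RPM, had identical values in all 8 libraries. The ratio of miR-7b-5p to miR-7a-5p lay between 0.929 and 0.959, that of miR-10b-5p to miR-10a-5p between 0.949 and 1.01, that of miR-181b-5p to miR-181d-5p between 0.850 and 0.921, and that of miR-196b-5p to miR-196a-5p between 0.900 and 1.03. Such copies are treated as uncertain.

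Alternatives tried were median-of-ratios scaling, no filter, a mean of at least 10 RPM, limma-voom on the implied reads, the sum of both arms, pseudocounts of 0.5 and 5, no day term, day as a linear term, each library or day pair left out, a linear trend over days and a contrast of late with early days. Added after the data were examined were the prior variance without the robust option, values scaled to reads outside the miR-290 cluster, day pairs left out of the test for a changing Dox effect and of the shares, the use of implied reads in limma-voom, the share of each list without its most abundant member, and tests on genomic clusters of hairpins within 10 kb.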

Results

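Mature miRNAs were profiled by small RNA sequencing during embryoid body (EB) differentiation of KH2-DGCR8 cells. KH2 is a mouse embryonic stem cell line built for doxycycline-inducible transgenes, here for DGCR8, the partner of DROSHA in the Microprocessor that cuts primary miRNA transcripts. EBs are aggregates in which stem cells leave pluripotency. Libraries were made at days 0, 1, 2 and 4 with and without Dox, 1 per condition, so no value below has a replicate of its own condition. The study asked what excess DGCR8 does to miRNA biogenesis. Values are the deposited scores, read here as RPM (miRNA reads scaled to 1 common total per library). The libraries rested on 362483 to 541342 implied reads, and between 630 and 751 of the 1099 miRNAs listed were above 0 in a library.

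The embryonic stem cell miRNAs of the miR-290 cluster dominated the libraries at day 0. miR-293-3p, the most abundant miRNA, stood at 116591 RPM without Dox and 109875 with Dox. miR-292a-5p, miR-292a-3p and miR-294-3p of the same cluster, among the 5 most abundant by mean, lay between 46735 and 63604 RPM in the day 0 libraries. miR-184-3p, second by mean, lay between 45057 and 67642 RPM in all libraries. Day was the main axis of difference: the first principal component of the 499 miRNAs with a mean of at least 10 RPM held 47.1% of the variance. On it, both day 0 libraries lay at -15.3 and -15.9, day 4 without Dox at 23.6 and day 4 with Dox at 12.5.

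Dox was compared with no Dox across the 4 days to ask which miRNAs moved with Dox, the inducer of the DGCR8 transgene. miR-210-3p, a miRNA known to be induced by hypoxia, had the lowest adjusted p: it fell by 2.48 on the log2 scale (SE 0.30, limma adjusted p = 5.85e-08). Without Dox it stood at 970, 271, 332 and 988 RPM at days 0, 1, 2 and 4, and with Dox at 93, 106, 136 and 65. The counting interval of the ratio lay below 1 on each day, so that it was lower with Dox by 15.3-fold (95% interval 10.8 to 22.3) at day 4 and by 2.44-fold (1.8 to 3.33) at day 2. The SE and p above lean on the trend over all miRNAs and do not show this spread of the ratio between days. In the other direction, miR-582-3p rose by 1.23 (SE 0.25, adjusted p = 2.77e-04), with 177, 225, 294 and 149 RPM without Dox and 336, 545, 517 and 567 with it. In all, 16 of 839 miRNAs differed, 11 higher and 5 lower with Dox, and the median change of all miRNAs was 0.03. Some of the higher calls were near-identical copies with equal or near-equal values, so there were fewer separate signals.

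DGCR8 messenger RNA is not read by small RNA libraries and was not analysed here. The nearest readout is miR-1306, whose hairpin lies in a coding exon of Dgcr8 (chromosome 16, 18284239 to 18284317, minus strand, mm10) and is cut by the Microprocessor. miR-1306-3p was listed at 5, 4, 5 and 11 RPM without Dox and 11, 17, 9 and 11 with it, and miR-1306-5p at 10, 13, 9 and 14 against 11, 25, 17 and 13. Neither passed the threshold (log2 changes of 0.90, SE 0.64, and 0.44, SE 0.55; adjusted p = 0.678 and 0.888). These levels are at most 13 reads in a library, and every counting interval of the ratio by day included 1.

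Among the other miRNAs that rose with Dox were both arms of miR-582, whose hairpin lies within Pde4d (chromosome 13, 109324744 to 109324824), with miR-582-5p up by 1.21 (SE 0.35). The Hox-embedded miR-196a-5p rose by 0.83 (SE 0.21), from between 422 and 665 RPM to between 879 and 1032, and the near-identical miR-196b-5p by 0.77 (SE 0.22), which cannot be separated from it. miR-196a-1-3p, from the other arm of the hairpin at chromosome 11, 96265164 to 96265265, rose by 1.09 (SE 0.30). miR-770-3p, in an exon of the imprinted non-coding RNA gene Meg3 (chromosome 12, 109563692 to 109563785), rose by 1.39 (SE 0.31). Its Dox to no-Dox ratio was 6.62, 2.81, 2.34 and 1.12 at days 0, 1, 2 and 4. The counting interval of day 4 (0.806 to 1.58) included 1. miR-669a-3p and miR-669o-3p, which had identical values in every library, rose by 1.53 (SE 0.36), and miR-669a-3-3p by 1.59 (SE 0.37), all from hairpins within Sfmbt2. Values of miR-669a-3-3p were near-equal to theirs, at 164 against 172 RPM at day 4 with Dox, so it cannot be separated from them. The ratio of miR-669a-3p was 2.67, 1.53, 2.47 and 7.78 at days 0, 1, 2 and 4, and the counting interval of day 1 (0.915 to 2.61) included 1. miR-1968-5p, within Grtp1, rose by 1.05 (SE 0.26). miR-3063-3p, in an exon of Igf2bp1, rose by 2.22 (SE 0.63), but rested on 1 or 2 implied reads on each day without Dox, under the level of 3 reads. Its fold depends on the pseudocount (2.37 with 0.5 and 1.54 with 5), and the counting intervals of days 2 and 4 included 1.

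Beside miR-210-3p, whose hairpin is at chromosome 7, 141221384 to 141221493, miR-542-3p of the X chromosome (53049403 to 53049487) fell by 1.09 (SE 0.26). It stood at 126, 376, 501 and 734 RPM without Dox and 82, 226, 342 and 131 with it, and without the day 4 pair its log2 change was -0.63 (adjusted p = 0.204). miR-679-5p of the Dlk1-Dio3 region (chromosome 12, 109715577 to 109715650) fell by 1.02 (SE 0.29). The other calls, miR-210-5p (fitted log2 change -2.82, SE 0.84) and miR-302c-5p (-2.47, SE 0.66), were listed at 0 with Dox on at least 1 day, so their folds depend on the pseudocount, and did not have 1 direction in all 4 days. The calls rested on how the spread was estimated: without the robust option 0 miRNAs passed in limma, with 71 at an unadjusted p under 0.05 against 88, and limma-voom on the implied reads called 20. Without the day term 0 passed (25 at an unadjusted p under 0.05), with day as a linear term 1 passed, and with the day 0, day 1, day 2 or day 4 pair left out 7, 10, 1 and 9 passed.

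**Figure D1:**
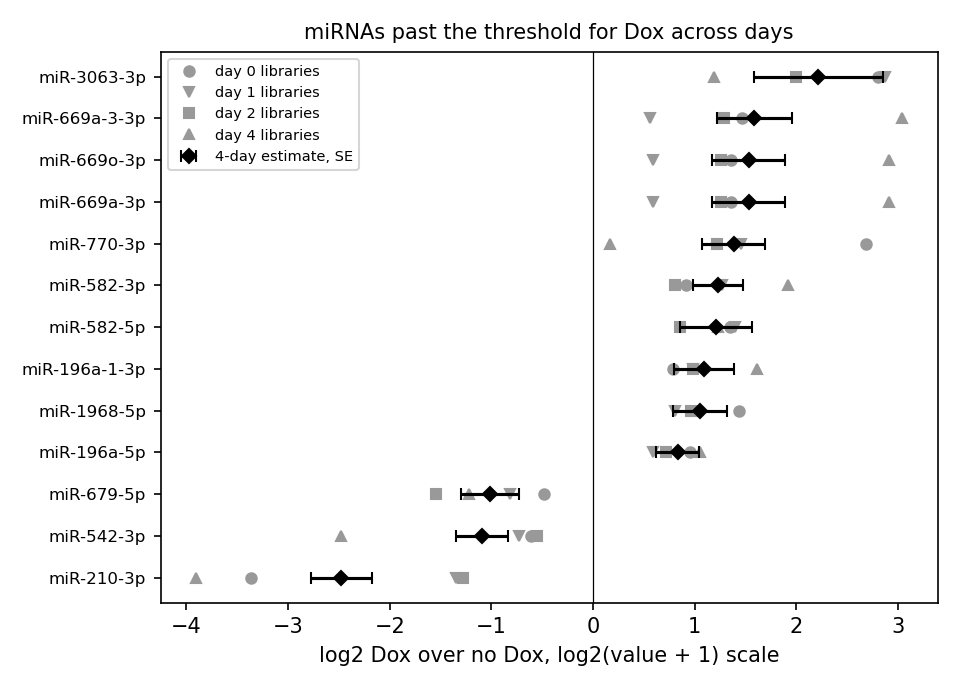
Log2 ratio of Dox to no Dox (x axis, log2(value + 1) scale) for the 13 miRNAs past the threshold that the naming rule took (y axis). Grey symbols are the ratio on each day, 1 library per treatment, and black diamonds the estimate over 4 days with its SE. miR-210-3p lies lowest, at -2.48, and miR-3063-3p highest, at 2.22.

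By list, the reduction with Dox was widest in the miR-302 cluster, pluripotency miRNAs that are high in epiblast-like cells (chromosome 3, 127545228 to 127545807). Its 9 tested members had a median log2 change of -1.36, although only miR-302c-5p passed the threshold (1 adjusted over the list alone), and camera gave adjusted p = 3.75e-04, or adjusted p = 0.683 with an estimated correlation. The 24 members of the miR-17 family clusters had a median of -0.23 and the 9 of the epithelial miR-200 family one of -0.35, with 0 members past the threshold in either, also adjusted over the list alone. Their camera adjusted p were 0.00486 and 0.00257, and with an estimated correlation both adjusted p were 0.683. miR-200b-3p stood at 4307, 5298, 3881 and 5562 RPM without Dox and 4267, 4554, 3182 and 2978 with it (adjusted p = 0.476), while miR-92a-3p, at 16313, 22653, 20160 and 25204 RPM without Dox, stood at 20980, 18842, 15398 and 17654 with it (adjusted p = 0.743), higher at day 0 and lower on later days. The 73 members of the Sfmbt2 cluster, rodent miRNAs of near-identical sequence within Sfmbt2, had a median of 0.24, with 2 of 73 higher, also adjusted over the list alone; miR-669a-3-3p is not counted in it (camera adjusted p = 0.00257, and adjusted p = 0.852 with an estimated correlation). By day, the median Dox ratio was 0.24, 0.05, -0.24 and 1.08 for the Sfmbt2 cluster at days 0, 1, 2 and 4, -0.001, 0.03, -0.23 and -0.59 for the miR-17 family clusters, and -0.18, -0.25, -0.29 and -0.60 for the miR-200 family, so each was widest at day 4. All 15 lists tested had adjusted p of at least 0.683 with an estimated correlation. With fry, which tests a list's own miRNAs and not against others, 0 lists moved 1 way (lowest adjusted p = 0.36) and 1, the p53-linked miR-34 list, changed in either direction (adjusted p = 0.00126). The members of that list that passed adjusted over the list alone rested on few implied reads, as given below.

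The other lists did not differ from the remaining miRNAs with Dox by camera, with adjusted p from 0.261 to 0.921. Of the 14 miR-290 cluster miRNAs none passed the threshold, also adjusted over the list alone, with a median of 0.02, a mean and test that pointed down, and a median of -0.005 under median-of-ratios scaling. Of the 13 let-7 family miRNAs, which promote differentiation, none passed, also adjusted over the list alone, and the median of 0.02 became -0.06 under that scaling. let-7a-5p had a log2 change of -0.19 (SE 0.21) and let-7g-5p one of 0.06 (SE 0.25). Of 18 miRNAs reported to bypass the Microprocessor none passed over all miRNAs and 1 was lower adjusted over the list alone, with a median of -0.09. miR-320-3p and miR-484 had log2 changes of -0.31 (SE 0.24) and -0.13 (SE 0.27). Among 102 Dlk1-Dio3 miRNAs 1 was higher and 1 lower, also adjusted over the list alone, with a median of -0.01, while the mean of 0.05 and the test pointed up. Of the 6 Hox cluster miRNAs 2 were higher, also adjusted over the list alone, miR-196a-5p and miR-196b-5p, and the median was 0.01, or -0.01 after that scaling. These 2 are near-identical copies that cannot be separated, and miR-196a-1-3p, which also passed, is not counted in the list.

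Among lineage markers, none of the 6 cardiac and skeletal muscle, 10 blood and endothelium, 11 neural or 6 endoderm miRNAs passed the threshold for Dox. Adjusted over the list alone, 1 endoderm miRNA was higher and 0 of the other 3 lists passed. The medians were -0.10, -0.02, -0.04 and 0.59. miR-192-5p, of the endoderm list, had a log2 change of 0.69 (SE 0.23, adjusted p = 0.105). None of the 14 fibroblast (feeder) markers passed (1 higher adjusted over the list alone), with a median of -0.19. Among them miR-22-3p had a log2 change of 0.58 (SE 0.19, adjusted p = 0.0806) and miR-21a-5p one of 0.43 (SE 0.16, adjusted p = 0.185). None of the 7 p53-linked miR-34 miRNAs passed, with 1 higher and 1 lower adjusted over the list alone. They were miR-34b-3p, at a log2 change of 2.00 (SE 0.62, adjusted p = 0.0550), and miR-449a-5p, at -2.04 (SE 0.67, adjusted p = 0.0806). Both rested on few implied reads. At days 0, 1, 2 and 4 miR-34b-3p had 3, 0, 1 and 10 without Dox and 9, 16, 2 and 23 with it. miR-449a-5p had 5, 4, 15 and 5 without Dox and 1, 1, 3 and 1 with it.

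Whether the Dox effect changed with day was tested next. The miR-302 miRNAs stood apart: miR-302b-3p was at 126 RPM without Dox and 145 with Dox at day 0, and at 12939 and 914 at day 4. Its Dox log2 ratio fell by 1.04 per day (SE 0.15, limma adjusted p = 3.39e-09). The ratio was 1.15, 1.03 and 0.683 at days 0, 1 and 2, and 0.0707 (95% counting interval 0.0643 to 0.0775) at day 4. A straight line over days is thus a rough summary, and the SE, which leans on the trend over all miRNAs, does not show its misfit. miR-302a-3p went from 78 and 41 RPM at day 0 to 4444 and 310 at day 4, and miR-302d-3p from 126 and 104 to 11363 and 800. Of the 9 cluster members 5 passed with a falling Dox ratio, 6 adjusted over the list alone, and the cluster's median Dox ratio was -0.91, 0.48, -0.89 and -3.84 at days 0, 1, 2 and 4. The day 1 median was the value of miR-302c-5p, which rested on 3 implied reads with Dox and 2 without. That day the cluster's share of reads was lower with Dox, at 0.0743% against 0.0844%.

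In all, 8 miRNAs passed, 6 with a falling and 2 with a rising Dox ratio; scaled to reads outside the miR-290 cluster 11 passed, 5 falling and 6 rising. The rising pair was miR-10a-5p and its near-identical copy miR-10b-5p, Hox-embedded miRNAs, by 0.59 per day each (SE 0.16, adjusted p = 0.0367). miR-10a-5p stood at 201 RPM without Dox and 689 with it at day 4, against 199 and 139 at day 0. The remaining one, miR-493-5p of the Dlk1-Dio3 region, went from 44 and 167 RPM at day 0 to 248 and 137 at day 4. By camera 7 of 15 lists changed, none with an estimated correlation. The Dox ratio rose with day in the miR-290 cluster (adjusted p = 1.63e-07, and adjusted p = 0.400 with an estimated correlation; 0 of 14 higher, 5 adjusted over the list alone) and the Sfmbt2 cluster (1.84e-08, and 0.478). It also rose in the Hox cluster miRNAs (0.0310, and 0.478) and fibroblast markers (0.00848, and 0.446). It fell in the miR-302 cluster (1.63e-06, and 0.478), the Dlk1-Dio3 cluster (4.31e-06, and 0.478) and the miR-17 family clusters (0.00189, and 0.446). Adjusted over the list alone 3 of the 24 miR-17 family miRNAs, 1 neural and 1 Dlk1-Dio3 miRNA had a falling ratio, 2 Hox cluster miRNAs and 1 muscle miRNA a rising one, and 0 in the remaining lists. The 8 other lists had camera adjusted p from 0.181 to 0.817, and with fry 0 lists moved 1 way (lowest adjusted p = 0.0711) and 5 changed in either direction. The calls rested on the day 4 pair: without it 0 miRNAs passed in limma (49 at an unadjusted p under 0.05) and 4 of the 8 slopes changed sign, to 0.076 for miR-302a-3p, 0.085 for miR-302a-5p, -0.046 for miR-10a-5p and -0.038 for miR-10b-5p, while that of miR-302b-3p was -0.37. 0 passed too without the day 2 pair (62 at an unadjusted p under 0.05), without the robust option (81) or when days 2 and 4 were set against days 0 and 1 (38), no filter gave 5, and limma-voom kept the call of 7 of the 8.

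**Figure D2:**
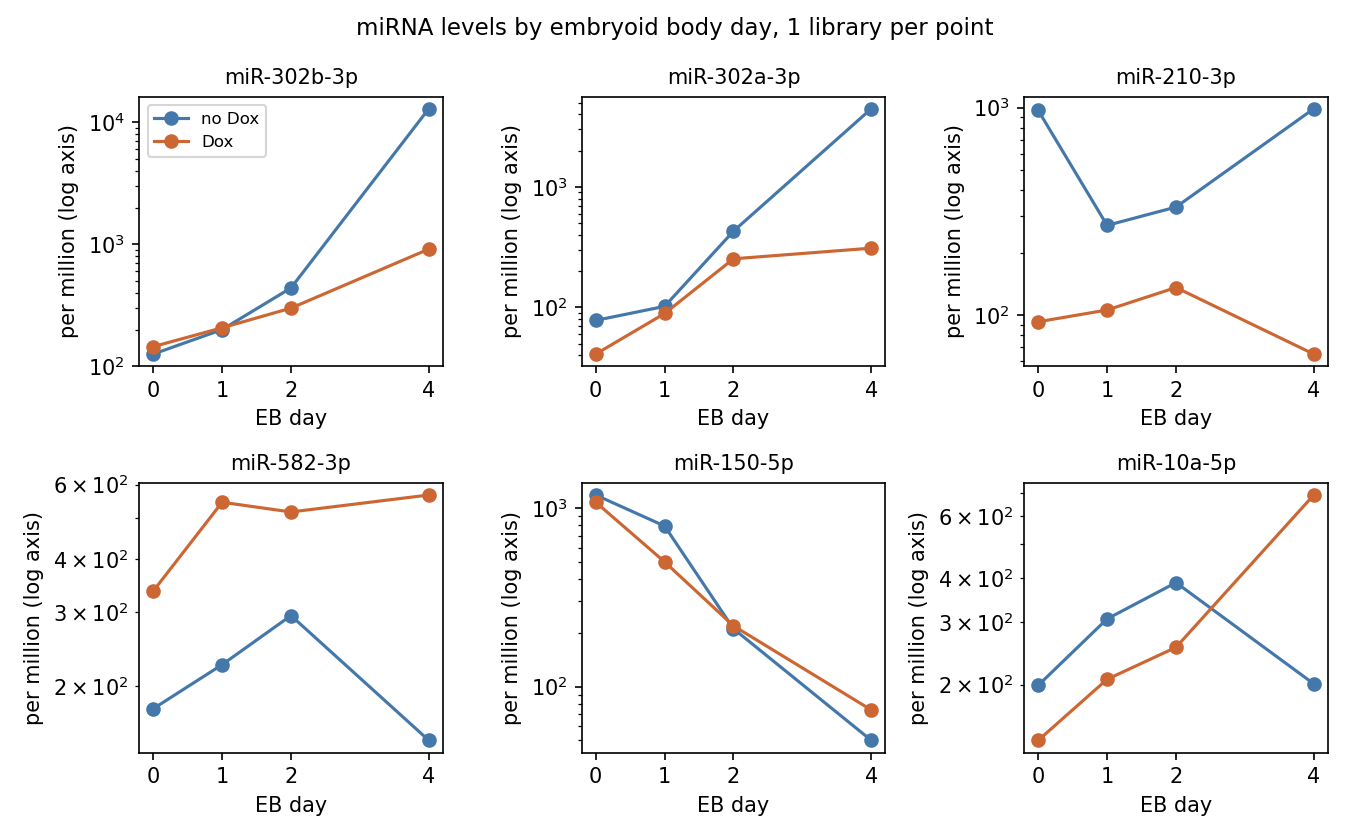
RPM (y axis, log scale) by EB day (x axis) without Dox (blue) and with Dox (orange), 1 library per point, for 6 miRNAs. miR-302b-3p reached 12939 RPM at day 4 without Dox and 914 with it, while miR-150-5p ended at 50 and 74.

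Within single days there was 1 library per treatment, so ratios are values without a test. Of the 499 miRNAs with a mean of at least 10 RPM, 98 (19.6%) had 1 direction in all 4 days, 47 higher and 51 lower with Dox, where signs drawn at random would give 12.5%. Across miRNAs, which are not independent replicates, the Dox log2 ratios of different days were weakly related, with Pearson's r from 0.04 (Spearman's rho 0.10) for days 1 and 4 to 0.37 (rho 0.28) for days 0 and 2, and a mean r of 0.18 over the 6 pairs of days. The share of miRNAs with a ratio of at least 2-fold in either direction was 18.0%, 13.2%, 16.2% and 22.2% at days 0, 1, 2 and 4.

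EB differentiation itself was compared as day 4 against day 0. miR-150-5p, a miRNA of mature lymphocytes, fell the most, by 4.19 on the log2 scale (SE 0.35, limma adjusted p = 2.50e-29), from 1185 and 1080 RPM to 50 and 74. miR-181c-5p fell by 2.51 (SE 0.32) and miR-181d-5p, whose values lay near those of miR-181b-5p, by 2.43 (SE 0.27), whereas miR-181a-5p rose by 3.99 (SE 0.63), from 10 and 11 RPM to 157 and 209. miR-7a-5p fell by 2.03 (SE 0.24), from 16938 and 26526 RPM to 5876 and 4566. Imprinted miRNAs of the Dlk1-Dio3 region rose, among them miR-381-3p by 1.46 (SE 0.23) and miR-300-3p by 1.66 (SE 0.23), to 29817 RPM without Dox. miR-21a-5p rose by 1.99 (SE 0.23), to 36898 and 53151 RPM.

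At day 4, 216 of 839 miRNAs differed from day 0, 184 higher and 32 lower, and the median change of all miRNAs was 0.56. Scaled by the median of ratios, which brought that median to 0.01, 161 differed, 100 higher and 61 lower, so the share of higher calls went from 85.2% to 62.1%. Scaled to reads outside the miR-290 cluster, an alternative chosen afterwards, there were 107 higher and 57 lower. At day 2, 145 differed (128 higher and 17 lower, median 0.48), against 51 and 51 with median-of-ratios scaling and 92 and 27 outside the miR-290 cluster. At day 1, 68 differed (59 higher and 9 lower, median 0.36), against 35 and 34 with that scaling. Without the robust option 157, 72 and 13 miRNAs passed at days 4, 2 and 1. With 1 library left out, the day 1 count was 22, 7, 33 and 107 without the no-Dox library of days 0, 1, 2 and 4, and 11, 34 and 108 without the Dox library of days 1, 2 and 4. The day 2 count was 46 and 1 without the no-Dox library of days 0 and 2 and 53 without the Dox day 2 library, and the day 4 count 118 without the no-Dox day 0 library.

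The miR-290 cluster (chromosome 7, 3218626 to 3220841) lost ground: 11 of 14 members fell and 0 rose, 13 adjusted over the list alone, with a median of -1.06. The camera adjusted p was 1.34e-14, or adjusted p = 0.368 with an estimated correlation. miR-293-3p fell by 1.14 (SE 0.21), miR-294-3p by 1.05 (SE 0.21) and miR-294-5p by 1.85 (SE 0.36). In the miR-302 cluster 5 of 9 rose, 9 adjusted over the list alone, with a median of 4.68 (camera adjusted p = 9.81e-04, and adjusted p = 0.531 with an estimated correlation). The 4 that did not pass over all miRNAs included miR-302b-3p, with a log2 change of 4.66 (SE 1.34, adjusted p = 0.125). Without Dox the median change of the cluster was 5.98 and with Dox 2.93. miR-302a-3p and miR-302c-3p, which passed narrowly (adjusted p = 0.0318 and 0.0477), lost their calls under median-of-ratios scaling (0.0658 and 0.0807), where 2 of the 9 members rose and the median was 4.09. Of the 102 Dlk1-Dio3 miRNAs 72 rose and 0 fell, 76 adjusted over the list alone, with a median of 1.52 (camera adjusted p = 2.33e-14, and adjusted p = 0.368 with an estimated correlation). After median-of-ratios scaling 43 of them rose, with a median of 0.93. As fixed, the list reaches back to miR-342 within Evl (chromosome 12, 108658620), before the first hairpin of the region's clusters at 109563692. In the hairpin clusters from Mir770 to Mir136, Mir341 to Mir370 and Mir379 to Mir3072, 16 of 22, 3 of 5 and 51 of 70 rose in RPM.

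Of 11 neural miRNAs 5 fell, including miR-124-3p by 2.33 (SE 0.45) and the near-identical miR-7a-5p and miR-7b-5p, 2 rose and 4 did not pass, the same counts adjusted over the list alone (camera adjusted p = 4.92e-04, and adjusted p = 0.368 with an estimated correlation). The 2 that rose were miR-9-5p and miR-128-3p, and under median-of-ratios scaling 6 fell and 0 rose. Among muscle miRNAs 2 of 6 rose, also adjusted over the list alone: miR-133a-3p, from 7 and 0 RPM to 91 and 31, and miR-1a-3p, listed at 0 in both day 0 libraries and at 39 and 22 at day 4 (camera adjusted p = 0.336 for the list). Of the 18 miRNAs reported to bypass the Microprocessor 7 rose, also adjusted over the list alone, with a median of 1.49 (camera adjusted p = 0.0703), among them miR-1983 by 0.93 (SE 0.32) and miR-1839-5p by 0.90 (SE 0.33). After median-of-ratios scaling 3 were higher and 1 lower. Of the 14 fibroblast markers, which include miR-21a-5p, 2 rose and 1 fell over all miRNAs and 2 rose adjusted over the list alone, with a median of -0.12, a mean of 0.04 and a test that pointed down (camera adjusted p = 0.115). Under median-of-ratios scaling 2 rose and 3 fell, with a median of -0.71. miR-143-3p, of the same list, stood at 2191 and 1960 RPM at day 0 and at 1004 and 1816 at day 4 (adjusted p = 0.0880).

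The remaining lists did not pass camera for day 4, with adjusted p from 0.0547 to 0.967. In the miR-17 family clusters 5 of 24 rose, also adjusted over the list alone, and 5 rose and 5 fell under median-of-ratios scaling; the risers included miR-18b-3p, up by 2.27 (SE 0.55), and miR-363-3p, up by 2.24 (SE 0.26). Of the let-7 family 1 of 13 rose, of the miR-200 family 2 of 9, of the p53-linked miR-34 list 3 of 7, of the Hox cluster miRNAs 2 of 6, and of the Sfmbt2 cluster 9 of 73, with 1 lower. Adjusted over the list alone these were 1, 2, 3, 2 and 7 higher and 0 lower, and under median-of-ratios scaling 0, 0, 1, 0 and 2 higher, with 3 Sfmbt2 miRNAs lower. The Hox calls were miR-10a-5p and miR-10b-5p, which at days 0 and 4 stood at 199 and 201 and at 199 and 204 RPM without Dox, and at 139 and 689 and at 137 and 685 with Dox, so the change lay in the Dox libraries. miR-34c-5p rose by 1.82 (SE 0.31). Of the blood and endothelium list 1 of 10 rose, miR-451a, and 2 fell, both arms of miR-150, and of the endoderm list 1 of 6 rose, miR-375-3p, and 1 fell, miR-194-5p, by 1.45 (SE 0.39), with the same counts adjusted over the list alone. Under median-of-ratios scaling 0 rose in either list, 3 fell in the blood and endothelium list and 2 in the endoderm list. miR-451a was listed at 0 in the libraries of days 0 to 2 and at 6 RPM in both day 4 libraries, near the level of 3 reads. The medians of 5 lists changed sign under median-of-ratios scaling: the miR-17 family clusters went from 0.35 to -0.25, the let-7 family from 0.33 to -0.27, the blood and endothelium list from 0.23 to -0.35, the endoderm list from 0.21 to -0.13 and the Sfmbt2 cluster from 0.53 to -0.001. Camera, which compares a list with the other miRNAs, pointed down for these 5 lists and the Hox cluster miRNAs although their RPM medians were above 0, as did the mean of the blood and endothelium list, at -0.64. With fry, which does not set a list against other miRNAs and so takes in the shift of the median, 5 lists moved 1 way at day 4. They were the miRNAs reported to bypass the Microprocessor (adjusted p = 0.00325) and the miR-290 cluster, miR-200 family, Dlk1-Dio3 cluster and neural list (0.0496 each), and 12 lists changed in either direction. Several of the highest changes were of low miRNAs. miR-488-3p, miR-653-5p and miR-877-5p were listed at 0 in both day 0 libraries, and at day 4 stood at 80, 77 and 19 RPM without Dox and 37, 6 and 17 with Dox.

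The share of reads per list shows these changes on a linear scale. The miR-290 cluster held 46.1% of reads without Dox and 40.5% with Dox at day 0, and 16.3% and 22.9% at day 4. The miR-302 cluster went from 0.0419% and 0.0329% to 3.58% and 0.237%, and the Dlk1-Dio3 cluster from 6.59% and 8.36% to 22.2% and 21.2%. Beside these shifts, the fibroblast markers went from 1.41% and 1.98% to 4.02% and 5.82%, most of it miR-21a-5p, at 3.69% and 5.31% at day 4. The other 13 markers held 0.563% and 0.513% at day 0 and 0.329% and 0.502% at day 4, and the median log2 change of the list was -0.12. The miR-302 cluster's share differed between Dox and no Dox by -0.866 points on average (SD 1.65), and by -0.041 without the day 4 pair. It was lower with Dox on each day, as was that of the miR-200 family, while the endoderm and Hox cluster shares were higher on each day. The share of the miRNAs reported to bypass the Microprocessor was lower on each day too, but without miR-1983 it was higher with Dox at days 1 and 4, and the mean difference went from -0.0243 to -0.00225 points. The Hox cluster miRNAs did not move as a group: their median log2 Dox ratio was 0, -0.28, -0.61 and 1.32 at days 0, 1, 2 and 4. At days 0 to 2 the near-identical miR-196a-5p and miR-196b-5p were higher with Dox, whereas miR-10a-5p and miR-10b-5p were lower. The Dlk1-Dio3 and miR-290 shares were each higher with Dox on 2 of 4 days, with mean differences of 0.502 (SD 1.94) and 0.0658 points (SD 5.19). The Dlk1-Dio3 difference was -0.177 without the day 1 pair, and the miR-290 difference -0.338 without the day 2 pair and -2.12 without the day 4 pair. They were 0.0603 and -0.296 points without miR-381-3p and miR-293-3p, the most abundant members. No list passed the exact sign-flip permutation test, whose smallest possible p with 4 days is 0.125; after Benjamini-Hochberg adjustment over the 16 lists the lowest p was 0.400. The Dgcr8 transcript hairpin, the list with too few members for the other tests, held between 0.0014% and 0.0042% of reads.

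**Figure D3:**
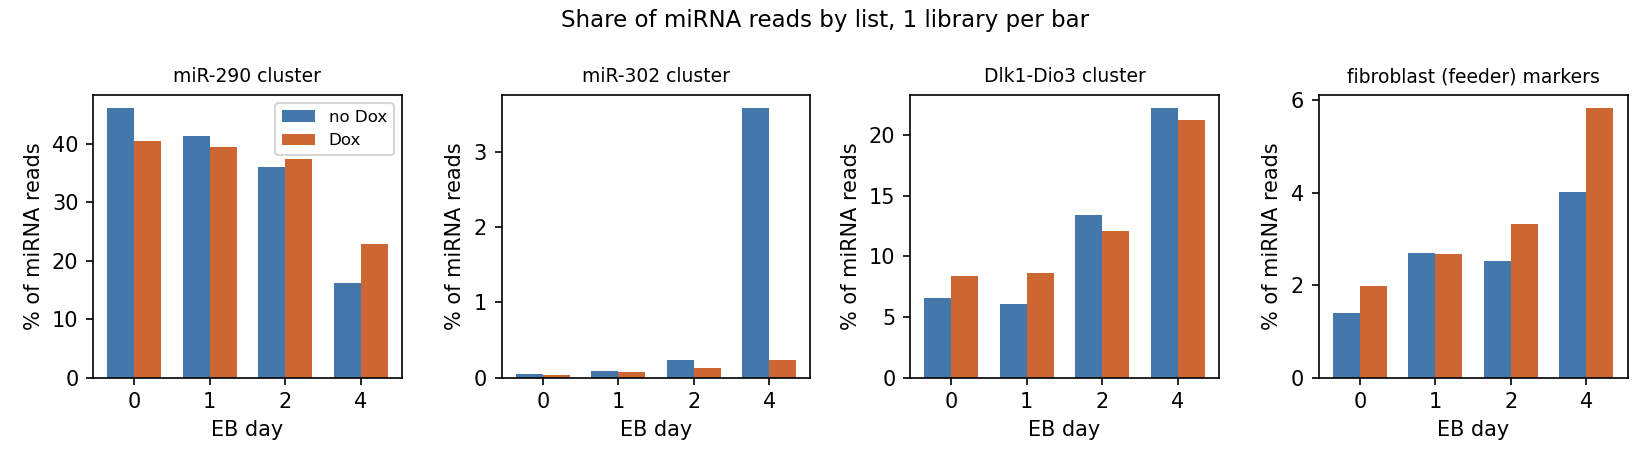
Percentage of miRNA reads (y axis, linear, different scale per panel) held by 4 lists by EB day (x axis) without Dox (blue) and with Dox (orange), 1 library per bar. The miR-290 cluster went from 46.1% to 16.3% without Dox, and the miR-302 cluster reached 3.58% at day 4 without Dox and 0.237% with it, while miR-21a-5p made up 3.69% and 5.31% in the fibroblast marker panel at day 4.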

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

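The tests on scaling, on the day of collection, on the spread at day 4, on counting error, on doxycycline alone and on the share of the miR-290 cluster were chosen after the results were seen; the correlation test for slower progress and the regroupings of libraries were set before. Results that stand out are those whose Dox effect differed between days by the test of treatment with day. The Dox log2 ratio changed per day by -1.04 for miR-302b-3p, -1.03 for miR-302c-3p, -1.001 for miR-302a-5p, -0.92 for miR-302d-3p and -0.81 for miR-302a-3p. It changed by -0.64 for miR-493-5p, and by 0.590 and 0.589 for miR-10a-5p and miR-10b-5p, which had near-equal values.

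The first pattern is the low miR-302 cluster with Dox at day 4. Scaling to RPM is argued against as its cause, since the median log2 ratio of all miRNAs between the day 4 libraries was -0.057 and that of the cluster -3.84. Slower progress of differentiation with Dox, the biological candidate, stays open: outside the cluster, the day 4 Dox ratio was related to the change from day 0 to day 2 with r = -0.161 across 490 miRNAs (bootstrap 95% interval -0.255 to -0.0599, Spearman's rho -0.19), between the bounds of -0.2 and -0.1 set beforehand. A Dox day 4 library collected early is not settled either. Over 244 miRNAs that changed at least 2-fold without Dox, its median progress towards the no-Dox day 4 library was compared with that of the Dox day 2 library. It was higher by 0.309 (interval 0.222 to 0.385), which lies above 0 but spans the bound of 0.3 that was set. At days 1, 2 and 4 median progress was 0.236, 0.353 and 0.662 with Dox. Without Dox it was 0.302, 0.583 and, by definition, 1. On this measure the Dox day 4 library lay closer to the no-Dox day 2 library than to that of Dox day 2. The progress measure favours the no-Dox libraries that chose the miRNAs. Over the 499 miRNAs with a mean of at least 10 RPM, Pearson's r between libraries gave the other order. For the Dox day 4 library it was 0.941 with Dox day 2 and 0.931 with no-Dox day 2. Both intervals are over miRNAs of single libraries, many of which share a cluster and are not independent, so neither covers variation between libraries. Such variation cannot be told apart from a Dox effect with 1 library per condition, and the day 4 ratios had the widest spread, an SD of 1.06 against at most 0.891 on other days.

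The second pattern is miR-210-3p, lower with Dox on every day. Counting error is argued against, because the highest upper bound of the ratio over the 4 days was 0.555, and scaling to RPM too, because the fold after median-of-ratios scaling was -2.50 (SE 0.32). Doxycycline itself or differences in culture cannot be told apart from DGCR8, since 0 of the libraries were Dox-treated cells without the transgene.

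The third pattern is the excess of miRNAs that were higher at day 4. The share of reads given up by the miR-290 cluster is a candidate explanation, as the median log2 change of all tested miRNAs was 0.56 scaled to all reads and 0.12 scaled to reads outside the cluster. No biological explanation was tested for what remained.

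Regrouping the libraries bears on the counts. Swapping the Dox labels within days gives 8 groupings, too few for a share under 0.05: for Dox across days 1 of the 8, the real one, gave as many calls, 16 against at most 1 in the others. For the change of the Dox effect with day 4 of the 8 gave as many, with 8 calls in the real one and up to 19 in the others. Without the day term the real grouping gave 0 calls, which all 35 splits of the libraries into 4 and 4 reach by definition, so that count says nothing about chance. The highest other, with 87 calls, set days 0 and 1 against days 2 and 4, which points to day as a structure of the samples.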

How the results depend on the processing

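The prior variance without the robust option, values outside the miR-290 cluster, lists without their most abundant member and the day pairs left out of the shares and of the test for a changing Dox effect were chosen after the data were examined. Median-of-ratios scaling and limma-voom on the implied reads each kept all 16 Dox calls, and gave 17 and 20. The Dox count was 0 without the robust option, 1 with day as a linear term and, without the pairing by day (no day term), 0; with a day pair left out it ran from 1 to 10, where fewer libraries alone lower the power. Of the 16 calls, 7, 7, 1 and 6 were shared without the day 0, 1, 2 and 4 pair. The 13 miRNAs taken by the Dox rule and both arms of miR-1306 kept their direction under each setting computed for single miRNAs, which left out summed arms and scaling outside the miR-290 cluster. The Dox rule required 1 direction in all 4 days. Those 13 therefore could not reverse when a day pair or the day term was dropped, day was made linear or the prior variance was changed. The day 1 count was 44 for summed arms and 13 without the robust option, and ran from 7 to 108 with 1 library left out. The day 2 count was 72 without the robust option and ran from 1 to 191, and the day 4 count ran from 118 to 218. The test for a changing Dox effect gave 5 calls with no filter, 0 without the robust option, 0 for late against early days and 0 to 12 with a day pair left out. With values outside the miR-290 cluster it gave 11, 6 with a rising and 5 with a falling ratio, from 2 and 6. Slopes changed sign without the day 4 pair, whose removal leaves no day beyond 2: to -0.046 for miR-10a-5p, -0.038 for miR-10b-5p, 0.076 for miR-302a-3p and 0.085 for miR-302a-5p. With day pairs left out these slopes ran to 0.838, 0.838, -1.26 and -1.46. List calls went from 4, 4 and 7, for Dox, day 4 and the change of the Dox effect, to 0, 0 and 0 with an estimated correlation. The miR-290 share difference with Dox went from 0.0658 to -0.380 points without miR-293-3p in the total and -0.296 without it in the list, and ran from -2.12 to 1.96 with a day pair left out, within its SD of 5.19. That of the Dlk1-Dio3 cluster ran from -0.177 to 1.11. The mean r between days was 0.164 to 0.218 over scalings and pseudocounts. The cause was not tested where none is given. Tests for raw counts were not run, as the values are rounded RPM, and scaling by library total is what the values already carry. Depth limits miRNAs under about 8.28 RPM, or 3 reads in the smallest library.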

Other observations

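Clusters of hairpins less than 10 kb apart were formed from the annotation and tested after the data were examined. On the X chromosome, the cluster from Mir450b to Mir322 (53047997 to 53054349), which holds miR-542, miR-503 and miR-351, had a median Dox log2 change of -0.62 over 9 miRNAs, 1 of them past the threshold (camera adjusted p = 9.28e-04, and adjusted p = 0.402 with an estimated correlation). At day 4 it held 0.151% of reads without Dox and 0.0506% with Dox, and it was lower with Dox on the other days too. The cluster from Mir743b to Mir465d (66777256 to 66822713) had a median of -0.79 over 20 low miRNAs, 0 past the threshold, with the same adjusted p values. It held at most 0.0405% of reads.

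With differentiation, 6 of 9 miRNAs from Mir363 to Mir106a on the X chromosome rose (camera adjusted p = 0.0124, and adjusted p = 0.381 with an estimated correlation), and the cluster's share went from 0.99% and 1.31% at day 0 to 3.46% and 2.18% at day 4. This cluster overlaps the miR-17 family list but is not wholly within it, since only 5 of the 24 miRNAs of that list rose. By contrast, 0 of 7 miRNAs from Mir17 to Mir19b-1 on chromosome 14 passed the threshold. From Mir99b to Mir125a on chromosome 17, 4 of 6 rose, among them miR-99b-5p by 1.43 (SE 0.27), let-7e-5p by 1.19 (SE 0.40) and miR-125a-5p by 1.17 (SE 0.31), with a camera adjusted p of 0.0938. These changes are in RPM, of which the median over all miRNAs was 0.56 higher, and were not repeated for clusters under other scalings. miR-23a-3p fell by 1.39 (SE 0.29), while miR-27a-3p of the same hairpin cluster had a log2 change of 0.12 (SE 0.25); the difference between them was not tested. The sensory-organ miRNAs from Mir182 to Mir183 held between 6.16% and 8.35% of reads in all libraries, with 0 of 6 past the threshold.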
